A study of Mus musculus with 9 samples.

How the data were processed

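Binding of the homeodomain proteins Hoxa13 and Hoxa11 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of wild-type ICR mouse embryos, with home-made antibodies. The series holds 9 libraries. Hoxa13 was precipitated from the autopod, the hand and foot region, at E11.0 (embryonic day 11.0), from whole limb buds at E11.5 and from limb buds at E12.5, with 1 library per stage. Hoxa11 was precipitated from limb buds at E11.5 in replicates 1 and 2. The other 4 libraries are input DNA, for which no file was analysed here. By their titles, Hoxa13 at E11.5 and Hoxa11 replicate 1 share 1 input library, and Hoxa11 replicate 2 has another. Per the labels' protocols, one commercial kit served for the libraries of E11.0 and E11.5, while those of E12.5 were made by an earlier published procedure. From E11.0 to E11.5 stage and dissected tissue therefore change together, from E11.5 to E12.5 stage and protocol, and from E11.0 to E12.5 all of them, so their effects on the lists cannot be told apart.

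Per the submitters' processing notes, CASAVA 1.4, Bowtie2 2.2.2, MACS2 2.1.0 and the mouse build mm9 were used. The notes as used here give no role, order, threshold or treatment of duplicates, and do not say whether the input was used in calling. Each file belongs to 1 library. The chromosome names in the files are those of mm9, and positions on chromosome 1 run past the end of that chromosome in the later build GRCm38. The deposited lists of Hoxa13 at the 3 stages and of Hoxa11 replicate 1 hold 3 columns, the chromosome, start and end of each peak, with no other value. The deposited list of Hoxa11 replicate 2 has 10 columns in the narrowPeak order of MACS2. Its score column, as the authors deposited it, equals the whole part of 10 times the −log10 q-value in 100% of peaks. It also gives the authors' fold enrichment, a ratio over the caller's background, and the deposited −log10 p-value and summit position. These values are the authors' own and were used only to describe and rank peaks within that list.

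Read depth per library is not given in the sources used here, and a peak count is not a depth. Intervals for shares of peaks are exact Clopper-Pearson intervals at 95%. They cover counting error over peaks and not the spread between embryos. Peaks are not replicates, so each test compares peak lists, not conditions. For Hoxa11 the labels do not say whether both replicates came from separate litters, so the spread between them may be technical.

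Overlap was counted when peaks shared at least 1 bp. The number of overlapping peaks was compared with 1000 circular shifts of one list, with 1 random offset per chromosome. The p-values are two-sided permutation values, 0.002 is the smallest they can give, and Benjamini-Hochberg adjustment ran over 20 such tests. Hoxa11 peaks of both replicates were those that overlapped each other, merged to single intervals. To compare stages at one list length, every Hoxa13 list was limited to 44699 peaks, the length of the shortest. Shares were then compared by Fisher's exact test with Newcombe's interval of the difference, or, for the same Hoxa11 peaks against several stages, by the exact McNemar test, adjusted over the 3 stage pairs. The McNemar interval rests on the exact binomial interval of the discordant peaks. Median ranks of shared and unshared peaks were compared with 100000 resamples. Clustering was compared with 1000 uniform placements within the occupied span of each chromosome.

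These tests, the alternatives and the rule for named items were fixed before the data were examined, with the departures listed here. The design ranked peaks by score, but 4 of the 5 lists hold no score, so peak width took its place there. In the scored list, width and score had a Spearman correlation across peaks of 0.549 over 1647 peaks, which are not independent replicates. The planned correlation of scores between replicates was computed on widths for the same reason. The rule names the 5 highest-ranked peaks of each Hoxa13 list and of the Hoxa11 peaks of both replicates, the 5 such Hoxa11 peaks without Hoxa13, and the 5 widest E11.5 peaks found at all stages. It also names the 10 windows of 1 Mb richest in Hoxa13 peaks of all stages and the 5 richest in Hoxa11 peaks of both replicates. Peaks were not assigned to genes and HOX motifs were not counted: the reference tables in hand are of GRCm38 and hold no sequence, and coordinates were not converted. The planned tests of gene lists and of the motif were therefore not run.

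Some choices were made after the data had been seen. Windows of 1 Mb on chromosomes 1 to 19, X and Y were called dense when their peak count exceeded the third quartile by more than 3 interquartile ranges. This was first tried over all 5 lists. That definition takes 136 windows, among them the windows of the HoxA, HoxC and HoxD clusters. It was then restricted to the 3 Hoxa13 lists, which gives 26 windows and none of the Hox clusters, in part because it spares those clusters. Overlaps, stage differences, replicate concordance, clustering and ranks of shared peaks were repeated without either set, and the Hox window counts without the 26 windows only. For clustering, the uniform placements then also avoided these windows. The Hox cluster windows were chosen after their counts had been seen, and fall outside the naming rule. Their positions come from general knowledge of mm9 and not from an annotation. Their peak counts were set against the mean of 10000 draws of 4 windows, and stages were compared within each window by an odds ratio with its exact interval, also with the windows moved by 500 kb. As the windows were chosen with their counts in view, these are descriptions and their p-values are not given. The shares on chromosome X were also compared only after the data had been seen and carry no test. Random draws of 44699 peaks in place of the widest were also added later.

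Scripts ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The overlap procedure was tested on simulated data with widths from Hoxa11 replicate 1 and Hoxa13 E11.5. With 800 query and 5000 target peaks, 0 of 20 independent pairs fell under p 0.05. A planted share of 30% came out at 31.62% to 32.5% in 5 pairs, chance overlaps included. Simulated peaks were placed uniformly, with fewer shifts than in the tests and a one-sided p. The simulation therefore does not show the error rate for clustered lists such as these.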

Results

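Hoxa13, a transcription factor needed to form the hand and foot, was mapped in the early autopod and in limb buds at 3 stages. Hoxa11, a related homeodomain factor with a role in the forearm and lower leg, was mapped in limb buds at E11.5. The Hoxa13 lists held 50890 peaks at E11.0, 143460 at E11.5 and 44699 at E12.5, and covered 13.9, 45.1 and 7.99 Mb. Their median widths were 245, 286 and 154 bp. Hoxa11 gave 2953 peaks in replicate 1 and 1647 in replicate 2, both with a median width of 283 bp. Read depth was unknown, and each Hoxa13 stage had a single library, so differences between stages have no replicate check. All positions are 1-based in mm9, and no gene annotation was attached to them.

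The first comparison asked how far Hoxa13 occupied the same sites at successive stages. By an overlap of at least 1 bp, most sites of the shorter lists met the long E11.5 list. At E12.5, 70.7% of Hoxa13 peaks (95% interval 70.3 to 71.2) met an E11.5 peak, against 2.77% on average when the lists were shifted. At E11.0 the share was 58.1% (57.7 to 58.6), against 3.25%. In the full lists, where E11.5 is by far the longest, fewer sites joined the outer stages: 30.7% of E11.0 peaks met an E12.5 peak, and 35.6% of E12.5 peaks met an E11.0 peak. Of the E11.5 peaks, 20.5% met E11.0 and 21.7% met E12.5. Each of the 6 shares exceeded every circular shift (permutation p = 0.002 each, adjusted p = 0.002). When at least 50% of both peaks had to overlap, no share was a majority and the order of the outer stages turned: 29.6% of E12.5 and 47.3% of E11.0 peaks met E11.5, and of the E11.5 peaks 16.8% met E11.0 and 9.23% met E12.5. Between the outer stages, 19.2% of E11.0 peaks met E12.5 and 21.9% of E12.5 peaks met E11.0. This rule needs partners of like width, and E12.5 peaks were the narrowest (median 154 bp, against 286 at E11.5 and 245 at E11.0). The turn therefore cannot be told apart from peak width. With the widest 44699 peaks of each stage, 35.7% of E11.5 peaks met E11.0 and 42.0% met E12.5.

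A core of Hoxa13 sites recurred at all 3 stages. It held 13646 peaks of the E11.0 list (26.8%), 13767 of E11.5 (9.60%) and 13760 of E12.5 (30.8%). If the overlaps with the other stages were independent of each other within a list, 9092, 6388 and 11252.2 peaks would fall in the core. The excess over these numbers was not tested. Shifting both other lists gave at most 0.0604% (permutation p = 0.002 for each list). Such shifts also break the pairwise overlaps, so they do not test the core beyond those. At one list length, the widest 44699 peaks of each stage, the core was 21.8% of E11.0, 22.0% of E11.5 and 22.1% of E12.5 peaks. Under 50% reciprocal overlap of full lists it shrank to 14.4%, 3.795% and 11.7%. In the full lists, the remaining E11.5 peaks fell into 17319 shared with E12.5 but not E11.0, 15712 shared with E11.0 but not E12.5, and 96662 (67.4%) found at E11.5 alone. The last share depends on list length, as E11.5 held 143460 peaks against 50890 at E11.0 and 44699 at E12.5. At one list length, 35.7% of E11.5 peaks met E11.0, 42.0% met E12.5 and 22.0% met both. The share at E11.5 alone was not counted there.

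**Figure D1:**
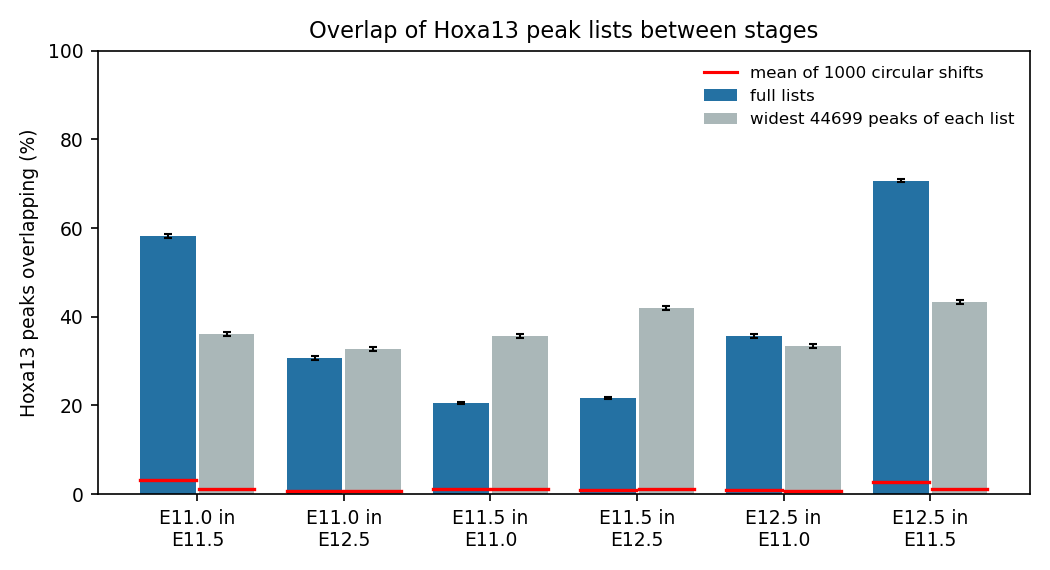
Share of Hoxa13 peaks (%, vertical axis) that met a peak of another stage, for each ordered pair of stages, with full lists (blue) and with the widest 44699 peaks of each list (grey). Error bars are exact 95% intervals over peaks and red lines the mean of 1000 circular shifts; the highest bar is E12.5 in E11.5 at 70.7%.

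At one list length, E12.5 Hoxa13 sites coincided with E11.5 more often than E11.0 sites did. Among the widest 44699 peaks of each stage, 43.2% of E12.5 and 36.1% of E11.0 peaks met E11.5, a difference of 7.17 percentage points (6.54 to 7.81, Fisher's exact test p = 1.31e-106). The direct overlap of the outer stages was 32.8% of E11.0 and 33.4% of E12.5 peaks, below the overlap with E11.5, but this order depended on the setting. A random draw keeps every E12.5 peak but only 44699 of 143460 E11.5 peaks, so shares meeting E11.5 fall by construction. In that draw, 30.7% of E11.0 peaks met E12.5 and 18.4% met E11.5, and 31.2% of E12.5 peaks met E11.0 and 22.0% met E11.5. The order also turned for E11.0 peaks among the widest 5000 (23.6% met E12.5, 21.5% met E11.5) and 10000 (27.1% and 24.9%), and for E12.5 peaks under 50% reciprocal overlap (20.2% met E11.0, 14.1% met E11.5). Under 50% reciprocal overlap, which narrow E12.5 peaks meet less easily, the difference in overlap with E11.5 turned. There E12.5 minus E11.0 was −14.3 points. It was 12.6 points with full lists and 3.62 with peaks drawn at random in place of the widest.

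The widest Hoxa13 peaks were long intervals at few places. No input file was analysed and repeated sequence was not screened out, so these intervals cannot be taken as the strongest Hoxa13 sites. At E11.0, 4 of the 5 widest lay near the start of chromosome 9, at 2999976 to 3005343, 3012659 to 3019602, 3019687 to 3031052 and 3031120 to 3038358. The widest of them spanned 11366 bp, and all of them met an E12.5 peak and no E11.5 peak. The fifth, on chromosome 2 from 3881689 to 3885720, was found at all stages and recurred among the widest at E11.5. The widest E11.5 peak, on chromosome 1 from 7379362 to 7384341, met E12.5 but not E11.0. At E12.5 the widest peak lay on chromosome 17 from 39979964 to 39984292 and met E11.0 but not E11.5. An interval on unplaced sequence (Un_random, 3643455 to 3648168 at E11.5) and intervals on 4_random were among the widest at both E11.5 and E12.5. The remaining named E12.5 peaks were on chromosome X from 121053261 to 121055998, found at all stages, and on chromosome 12 from 8638071 to 8640059, absent at E11.0. Of the 5 widest E11.5 peaks found at all stages, 3 lay on such unplaced sequence. The others were the chromosome 2 interval and one on chromosome 9 from 114081695 to 114085712.

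Among windows of 1 Mb, recurrent Hoxa13 sites were most frequent on chromosomes 4, 8 and X. Chromosome 4 held 56 E11.5 peaks of the core between 146000001 and 147000000, and 50 in the window before it. Next came chromosome 8 from 19000001 to 20000000 with 44. Chromosome X gave 5 of the 10 richest windows, starting at 3000001, 4000001, 30000001, 120000001 and 121000001, with 34 to 39 core peaks each. Y_random from 17000001 to 18000000 held 36, and chromosome 5 from 15000001 to 16000000 held 34. Of these 10 windows, 9 were also dense by total count in at least one Hoxa13 list, a definition made after the data were seen. The Y_random window lay outside the chromosomes scored for density. Its 87 peaks at E11.0 and 138 at E12.5 also exceeded the bounds for a dense window, 77 and 61. The share of Hoxa13 peaks on chromosome X was 6.40% at E11.0, 3.16% at E11.5 and 4.48% at E12.5. Without the 26 dense windows it was 4.25%, 2.78% and 2.83%.

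Hoxa11 binding was compared between its replicates next. Replicate 2, the shorter list, met replicate 1 at 64.6% of its peaks (62.2 to 66.9), and replicate 1 met replicate 2 at 35.8% (34.0 to 37.5). Shifted lists gave 0.323% and 0.192% (permutation p = 0.002 each). Merging the matched peaks left 1023 Hoxa11 sites seen in both replicates. In replicate 2, the authors' fold enrichment had a median of 4.21 over the 1064 peaks met by replicate 1 and 3.54 over the 583 that were not. Across 1056 matched replicate 1 peaks, the widths of both replicates had a Spearman correlation of 0.501, a description across peaks that are not independent.

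The strongest replicated Hoxa11 site by the authors' score lay on chromosome 9 from 29126172 to 29126784, with a fold enrichment of 16.6 and −log10 q of 163.5. It was followed by chromosome 12 from 9265156 to 9266052, at 17.6-fold, and chromosome 3 from 6381507 to 6382977, at 17.7-fold, the last of the 5 named sites by score. All of these met Hoxa13 at every stage, as did the site on Un_random from 3643433 to 3648129, at 6.59-fold. The site on chromosome 10 from 98633049 to 98634126, at 15.8-fold and next in score after chromosome 12, met no Hoxa13 peak at any stage.

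Most replicated Hoxa11 sites coincided with Hoxa13 binding. Of 1023 sites, 810 (79.2%, 76.6 to 81.6) met a Hoxa13 peak of the same stage, E11.5. At E12.5 the number was 662 (64.7%, 61.7 to 67.6), and at E11.0 it was 313 (30.6%, 27.8 to 33.5). Shifted lists gave 4.92%, 1.52% and 1.89% (permutation p = 0.002 each, adjusted p = 0.002). The single lists gave like shares at E11.5, 71.0% in replicate 1 (69.4 to 72.7) and 70.8% in replicate 2 (68.5 to 72.98). Hoxa13 at E11.5 and Hoxa11 replicate 1 share an input library by its title, and the effect of a shared input cannot be simulated from peak lists, so part of the excess may come from it. Under 50% reciprocal overlap the E12.5 share was 41.6% and the E11.0 share 18.1%.

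**Figure D2:**
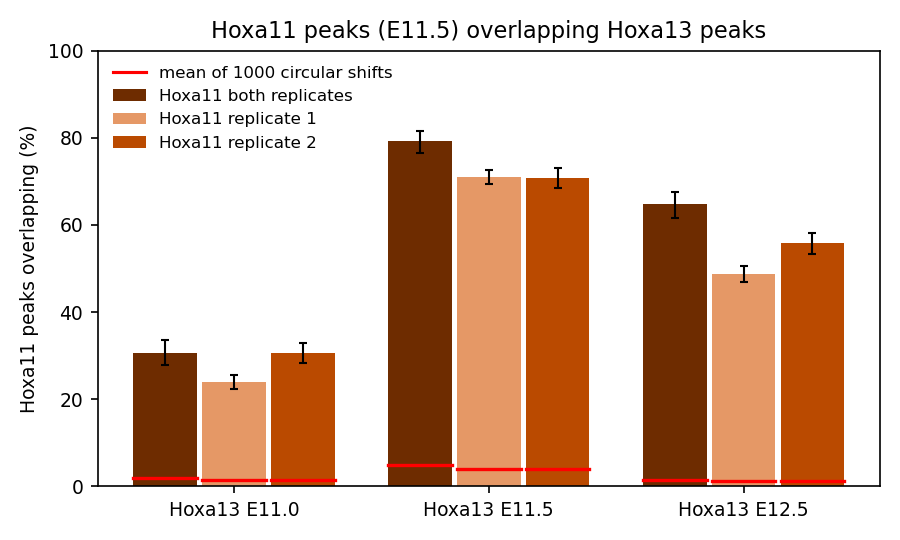
Share of Hoxa11 peaks (%, vertical axis) that met a Hoxa13 peak at each stage, for peaks of both replicates and for each replicate's full list. Error bars are exact 95% intervals over peaks and red lines the mean of 1000 circular shifts; the bars for both replicates stand at 30.6%, 79.2% and 64.7%.

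By combination of stages, 348 of the 1023 Hoxa11 sites met Hoxa13 at E11.5 and E12.5 but not E11.0, and 277 met it at all 3 stages. A further 167 met it at E11.5 only, 30 at E12.5 only and 11 at E11.0 only. E11.0 and E11.5 without E12.5 accounted for 18 sites, and E11.0 and E12.5 without E11.5 for 7. The remaining 165 sites (16.1%, 13.9 to 18.5) met no Hoxa13 peak. Their median fold enrichment was 3.604, against 4.34 for the 858 sites with Hoxa13. The highest-scoring of these sites after that on chromosome 10 lay on chromosome 12 from 103765291 to 103765738 (9.46-fold) and chromosome 4 from 24765690 to 24766077 (9.20-fold). Those on chromosome 18 from 7608622 to 7609684 (6.45-fold) and chromosome 5 from 38309171 to 38309530 (5.14-fold) came next.

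At one list length, the same Hoxa11 sites coincided with E11.5 and E12.5 Hoxa13 more often than with E11.0. With the widest 44699 peaks of each stage, the shares were 66.0% at E11.5, 64.7% at E12.5 and 29.3% at E11.0. E11.5 exceeded E11.0 by 36.7 points (34.3 to 38.5, exact McNemar test, adjusted p = 1.41e-84), and E12.5 exceeded E11.0 by 35.4 points (33.1 to 37.2, adjusted p = 1.53e-82). E11.5 and E12.5 differed by 1.27 points (−1.63 to 4.14, exact McNemar test, adjusted p = 0.413), but this comparison turned on the setting: E11.5 was higher past the threshold by 14.5 points with full lists, 13.7 under 50% reciprocal overlap, 7.28 with the union of replicates, 3.94 and 3.61 without the 26 and the 136 dense windows, and 8.84 without Hoxa11 replicate 2. With full lists E11.5 exceeded E11.0 by 48.6 points (46.6 to 50, exact McNemar test, adjusted p = 3.11e-127). With 44699 peaks of each list drawn at random, out of 143460 at E11.5, E11.5 minus E11.0 was −1.86 points (−5.43 to 1.75) and E11.5 minus E12.5 was −38.8. That draw keeps every E12.5 peak, so the thinner E11.5 list lowers both values by construction. E12.5 minus E11.0 was 37.0 points with random peaks and 23.4 with the union of both replicates, its lowest value.

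Counted from the Hoxa13 side, the same Hoxa11 sites gave the same contrast, which is not a second line of evidence. Of E11.5 Hoxa13 peaks shared with E12.5 but not E11.0, 361 of 17319 (2.08%, 1.88 to 2.31) held a replicated Hoxa11 site. Of those shared with E11.0 but not E12.5, 20 of 15712 (0.127%, 0.0778 to 0.197) did, an odds ratio of 16.7 (10.6 to 27.7, Fisher's exact test p = 6.61e-76). Peaks of all 3 stages held one in 293 of 13767 cases (2.13%), and peaks of E11.5 alone in 177 of 96662 (0.183%). The E11.0 tissue was the autopod and the later tissue the limb bud, and E12.5 was also prepared by another protocol, so these cannot be separated.

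**Figure D3:**
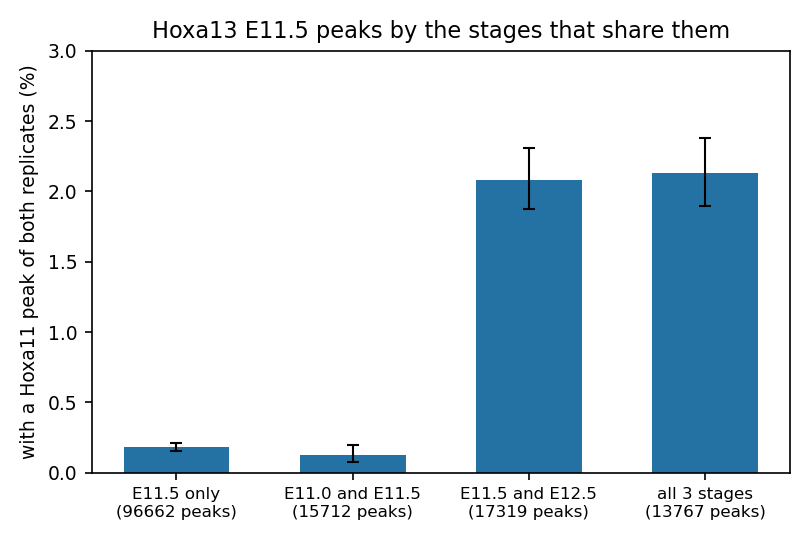
Share of Hoxa13 E11.5 peaks (%, vertical axis) that held a Hoxa11 peak of both replicates, by the stages at which the Hoxa13 peak was found. Error bars are exact 95% intervals over peaks; both classes with E12.5 lie above 2%, at 2.08% and 2.13%, and both without it at 0.183% and 0.127%.

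Hoxa11 sites seen in both replicates met Hoxa13 at E11.5 more often than sites seen in one. The shares were 79.2% of 1023 and 64.2% of 2480, a difference of 15.03 points (11.8 to 18.1, Fisher's exact test p = 6.43e-19). Among the unmatched sites, 66.7% of 1897 from replicate 1 and 55.9% of 583 from replicate 2 met Hoxa13. Under 50% reciprocal overlap the difference was 29.2 points. Replicated sites are merged intervals with a median width of 438 bp, against 256 and 247 bp for unmatched peaks of replicates 1 and 2. An overlap of 1 bp is easier for wider intervals, so part of the 15.03 points may come from width.

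In every list, peaks shared with another list of the same protein ranked higher than peaks that were not. The median width percentile of shared Hoxa13 peaks was above that of unshared ones by 19.1 at E11.0, 32.0 at E11.5 and 21.7 at E12.5. For Hoxa11 the gap was 35.4 by width in replicate 1 and 29.5 by the authors' score in replicate 2 (permutation p = 1e-05 in each list, the smallest the resamples can give). A wider peak has more sequence to be met by. Within the narrower 50% of each list the gaps were smaller, from 3.47 at Hoxa13 E11.0 to 13.8 in Hoxa11 replicate 2, and permutation p was at most 0.00038. In the 4 lists ranked by width, this split narrows the rank itself, so smaller gaps are built in and the split cannot remove the effect of width. In replicate 2, ranked by score, the gap was 31.3 in the wider 50%, against 29.5 in the whole list.

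Peaks of both proteins had near neighbours more often than uniform placement along the chromosomes gave. That placement takes no account of sequence where no peak can be called, so an excess over it does not by itself show grouped binding. A neighbour within 10 kb was found for 22.5% of Hoxa11 replicate 1 peaks and 25.6% of replicate 2 peaks, against 3.21% and 2.42% under uniform placement. For Hoxa13 the shares were 46.2% at E11.0, 73.4% at E11.5 and 40.5% at E12.5, against 33.2%, 68.6% and 29.7% (permutation p = 0.002 in each list). Lists of unequal length are not comparable here, and at 1647 peaks each the share was 30.97% for E11.0, 9.65% for E11.5 and 14.8% for E12.5. Without the 26 dense windows the share was 18.8% in either Hoxa11 replicate, and without the 136 it was 11.3% in replicate 1 and 11.2% in replicate 2, against 3.01% and 2.54% under placement that avoids them (permutation p = 0.002 each). Windows picked for their counts take clustered peaks with them, so some fall is built in. Within 50 kb the E11.5 share of 98.5% lay below the 99.3% of uniform placement. The 5 windows richest in replicated Hoxa11 sites were 4 windows on chromosome X and the first of 4_random. The chromosome X windows start at 121000001, 120000001, 92000001 and 122000001, with 25, 23, 19 and 14 sites, and 4_random held 11. Replicate 2 had 9.29% of its peaks on chromosome X and replicate 1 had 5.32%, and without the dense windows 1.02% and 0.644%.

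The 1 Mb windows around the Hox gene clusters were examined after their counts had been seen, so the values given for them are descriptive and no p-value applies. Without an annotation, sites in a window were not placed inside or outside its cluster. The 1 Mb windows that hold the HoxA, HoxB, HoxC and HoxD clusters contained 16 replicated Hoxa11 sites, against 1.55 in random sets of 4 windows (10.3-fold). The HoxA window on chromosome 6 held 7 of them, that of HoxD on chromosome 2 held 4, that of HoxC on chromosome 15 held 3 and that of HoxB on chromosome 11 held 2. In the HoxC window, the site from 102844833 to 102845401 was 11.3-fold enriched and met Hoxa13 at all stages. In the HoxD window, the sites from 74218811 to 74219338 (9.18-fold), 74535107 to 74535634 (6.87-fold) and 74976197 to 74976895 (11.6-fold) met Hoxa13 at E11.5 and E12.5 but not E11.0. The strongest site in the HoxA window, from 52176071 to 52176864 (5.81-fold), met Hoxa13 at every stage. Of the 16 sites, 14 met a Hoxa13 peak at E11.5.

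For Hoxa13, the 4 windows held 332 E11.5 peaks (1.502 times the mean of the draws), 105 at E12.5 (1.55 times) and 72 at E11.0 (0.933 times). In the HoxA window the list share was higher at E12.5 than at E11.0, with 38 against 20 peaks (odds ratio 2.16, 1.23 to 3.93). With the windows moved by 500 kb the counts were 27 and 23 (odds ratio 1.34, 0.738 to 2.44). E11.5 against E11.0 at HoxA gave an odds ratio of 2.02 (1.25 to 3.44), and 1.62 after the move (1.02 to 2.67). At HoxD the counts were 44 and 34 (odds ratio 1.47, 0.921 to 2.38), and at HoxB and HoxC the intervals also included 1. The windows next to HoxA and HoxD held 2, 3, 1 and 6 replicated Hoxa11 sites.

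**Figure D4:**
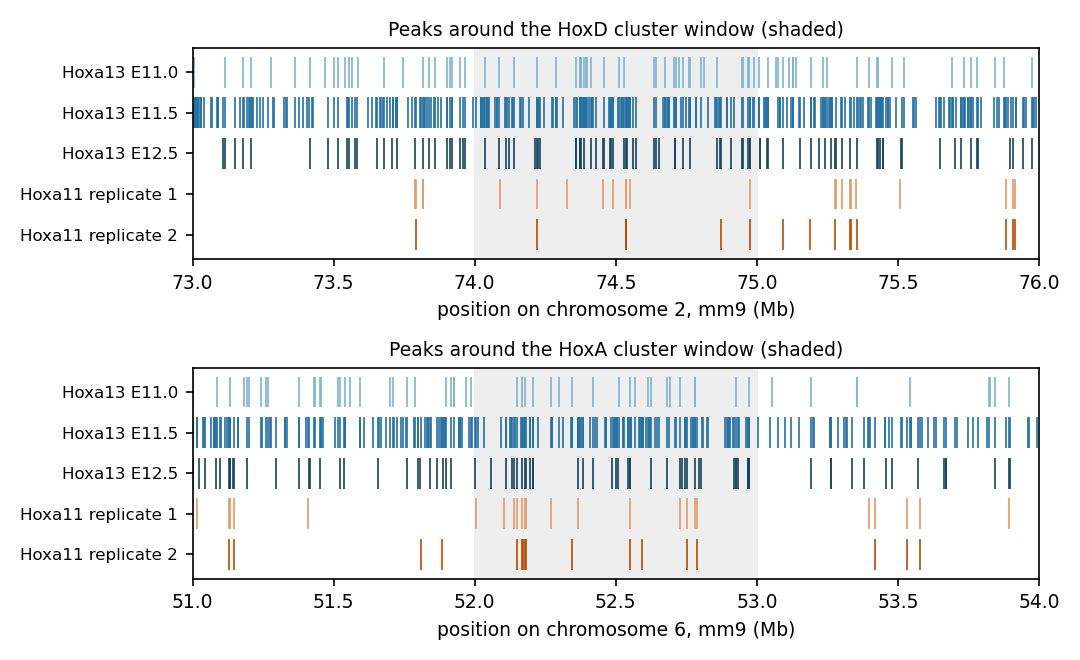
Positions of peaks (vertical ticks) of the 5 lists along chromosome 2 from 73 to 76 Mb and chromosome 6 from 51 to 54 Mb, in mm9 (horizontal axes, Mb). The shaded 1 Mb windows hold the HoxD and HoxA clusters; the HoxD window has 129 Hoxa13 peaks at E11.5 and the HoxA window 114.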

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

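The tests of dense windows and of the shared input library were chosen after the results they bear on had been seen, and those of repeated calls and of peak width were set down before their own outcome was known. Each pattern was found and tested on the same lists.

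The first pattern is that Hoxa11 sites met Hoxa13 at E12.5 more often than at E11.0, by 35.4 points at one list length. More unrepeated calls at E11.0 are argued against as the whole explanation of it. E11.5 peaks repeated at one other stage were alike in number (17319 with E12.5, 15712 with E11.0). Among them the odds ratio for a Hoxa11 site was 16.7 in favour of E12.5 (10.6 to 27.7). Likewise argued against as the whole explanation are peak width, with a pooled odds ratio of 15.9 (10.1 to 25) over 10 strata of E11.5 width, and dense windows, with 36.1 points left without them (34.0 to 37.6). Both odds ratios recount the Hoxa11 sites of the pattern itself and are no separate evidence for it. Of these, only dense windows were also tested for the other flagged differences, and are argued against there too: Hoxa13 peaks at E12.5 met E11.5 more often than E11.0 peaks did by 7.17 points (8.02 without dense windows, −14.3 under reciprocal overlap), and Hoxa11 sites met E11.5 more often than E11.0 by 36.7 points (40.1 without dense windows, 48.6 with full lists, −1.86 with random peaks). A background common to the E11.0 and E11.5 libraries, which share a kit, may fill the class of peaks without Hoxa11 and stays open, as does antibody quality at each stage. The Hoxa11 libraries were made with that kit too, and E11.5 peaks shared with E11.0 but not E12.5 held a Hoxa11 site in 0.127% of cases. Such a background would have to be missing from the Hoxa11 lists, but these hold only 2953 and 1647 peaks, against 143460 for Hoxa13 at E11.5. E11.5 peaks found at that stage alone held a Hoxa11 site in 0.183% of cases. The low share therefore cannot decide whether the class is background. The biological difference the design names, E11.0 autopod against later limb bud, is untested, because stage changes with tissue from E11.0 to E11.5 and with tissue and protocol from E11.0 to E12.5.

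The second pattern is that most Hoxa11 sites met Hoxa13 at E11.5. The input library shared with replicate 1 is argued against as the whole explanation, since replicate 2, with another input, reached 70.8%, against 3.98% in shifted lists. Between the full lists the difference was 0.251 points (−2.46 to 3.01), an interval that ignores the peaks found in both. Among unmatched sites the shares were 66.7% in replicate 1 and 55.9% in replicate 2. As part of the overlap the shared input may contribute, because unmatched replicate 1 sites met E11.5 without E12.5 more often than unmatched replicate 2 sites did (odds ratio 1.31, 1.05 to 1.64, Fisher's exact test p = 0.0132). Dense windows do not account for it, with a share of 79.5% (76.8 to 82.1) once they were left out. Cross-reaction of the antibodies, and open chromatin that any antibody recovers, were not tested. The lists come from separate libraries of limb bud tissue, so a shared peak does not show binding in the same cells. Joint binding of both proteins therefore remains a hypothesis.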

How the results depend on the processing

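Of 257 alternative values, 238 kept the direction and the side of the 0.05 threshold (or stayed within 1.5 times a count) and 19 did not. The 257 include 20 values of the Hox windows, where a p served only to sort them and tests nothing. Leaving out dense windows by either definition, drawing random peaks and moving the Hox windows were chosen after seeing the data. No alternative changed a call for replicate concordance or the ranks of shared peaks. Nor did any for the overlaps of Hoxa13 stages, of Hoxa11 replicates or of Hoxa11 with Hoxa13, or for the all-stage core. The overlaps and the core hold 48, 14, 33 and 24 of the 257 values, in that order. Every p among them was the smallest the shifts can give, so their calls do not test the size of a share. The share of Hoxa13 E12.5 peaks meeting E11.5 ranged from 29.61% to 71.75%, and the core from 3.795% to 22.02% of E11.5 peaks. All of these counted as kept. The excess of E12.5 over E11.0 in Hoxa11 overlap ranged from 23.4 to 37.0 points.

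The E12.5 minus E11.0 difference among Hoxa13 lists turned to −14.3 points under 50% reciprocal overlap. The Hoxa11 difference of E11.5 minus E12.5, 1.27 points, became 13.7 under reciprocal overlap, 14.5 with full lists, 7.28 with the union of replicates, 3.94 without the 26 dense windows and 3.61 without the 136, all past the threshold. It was −0.293 with 5000 peaks, −0.978 with 10000 and −38.8 with random peaks, and 1.88 to 8.84 when one Hoxa11 replicate was left out, past the threshold without replicate 2. E11.5 minus E11.0 was −1.86 with random peaks and 48.6 with full lists (exact McNemar test, adjusted p = 0.325 and 3.11e-127). E11.5 clustering within 50 kb was 98.5%, below chance. The E11.0 count in the Hox windows was 83 after a move of 500 kb, 1.08 times the mean of the draws in place of 0.933 times, and the E12.5 count of 105 was 1.59 times the mean without dense windows. After the same move the HoxA odds ratios against E11.0 fell to 1.34 for E12.5 and 1.62 for E11.5. For the 136 windows the Hox counts were not compared, since 3 of the 4 clusters are among them. Replicated Hoxa11 sites numbered 525 in the top 50% of the lists and 638 without the 136 windows, and those without Hoxa13 77 in the top 50%. Reciprocal overlap needs peaks of like width, which the narrow E12.5 peaks meet less easily. The random draw keeps 44699 of 143460 E11.5 peaks and every E12.5 peak, so lower E11.5 shares follow from the draw itself. Causes of the other changes were not tested.

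Without the dense windows the E12.5 list held 42738 peaks (26 windows) or 39883 (136 windows), and 43869 on chromosomes 1 to 19, X and Y, against 44699 for the others. The gene list and motif alternatives were not run. No paired analysis was possible because each Hoxa13 stage has 1 library, so the groups compared share at most 1 replicate number, and no input file was analysed here. Read depth is unknown, so its effect on list length was not assessed.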

Other observations

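The test in the second paragraph was chosen after the result it bears on had been seen. Neighbouring windows showed that Hoxa11 binding around HoxD was not confined to the window of the cluster. The window after it, from 75000001 to 76000000 on chromosome 2, held 6 replicated sites and the cluster's own window 4. These flanks were among the windows looked at before the cluster windows were chosen, and no test was run on them.

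Of the 20 windows of 1 Mb dense at E11.0 and the 18 dense at E12.5, 12 were dense at both, and none was dense at E11.5; by rank, 19 of the 20 stood above the 90th percentile at E12.5, 3 at E11.5, 5 in Hoxa11 replicate 1 and 6 in replicate 2. Reads from multi-copy sequence may pile up there whatever the antibody, in which case the windows should also be dense for Hoxa11, but their median percentile was 67.7 by replicate 2 peaks, below the bound of 75 that had been set down as arguing against this, and 0 by replicate 1 peaks. The reading was changed after the replicate 2 value was seen, from a rule on the median to one on the quartiles, because single windows ran from 0 to 99.96 in both replicates and a window with 1 replicate 2 peak already stands at 67.7. On the bound as originally set down the explanation would be argued against. Over all windows, however, the median count was 0 in either Hoxa11 list, and a window without a Hoxa11 peak stands at percentile 0. Lists this sparse cannot decide the question, and the replicate 1 median of 0 does not count against multi-copy sequence. On the changed reading windows that go both ways decide nothing, and multi-copy sequence cannot be told apart from other causes. No biological explanation was tested.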
